A study of Oryzias latipes with 108 samples.

How the data were processed

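Gene expression was measured in medaka (Oryzias latipes) fry of the laboratory strains NIES-R and Hd-rR. Per the labels, samples were taken at hatching (0 days post hatching, dph) and at 2, 4, 6 and 8 dph from fry that had or had not been given food. The 18 groups of strain, day and food hold 6 libraries each, 108 in all. Per the labels' protocols, RNA came from the whole body, was kept in a stabilising solution before extraction, and 180 ng of it went into Lasy-Seq, a method in which each sample is reverse transcribed with its own index and the products are then combined for the later steps. Hatching samples carry the feeding label and are treated as a group of their own here. The labels do not say whether a sample was 1 fry or several, or which samples shared a tank, so p-values measure the spread between these samples.

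Per the file headers, the authors deposited estimated counts made with salmon, 1 column per library and 1 line per Ensembl gene identifier, with 23649 identifiers in all. The values are whole numbers as deposited, so no rounding was needed. The submitters' processing notes name fastp 0.21.0, R 4.4.0 and Seurat 5.0.0. The salmon version, the transcriptome build and the annotation are not given in the sources used here. It is therefore not known whether reads of both strains match the transcriptome equally well, which bears on direct comparisons of the strains. A deposited sample table gives the total count, the number of genes detected and a well of a 96-well plate for each library, and its totals equal the sums of the count columns. The wells run through 1 plate for label numbers 201 to 296 and start again for label numbers 301 to 312. These 12 libraries are the 6 Hd-rR unfed libraries of 6 dph and the 6 of 8 dph, and no other group has such a library. They are taken here to come from a second plate, which no source states, and the column names carry 1 sequencing lane for all libraries. No fit can therefore hold the plate as a term beside the group.

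Total counts ranged from 291874 to 11235233 per library, with a median of 4503921. There were 2 libraries below 1501307, the limit set at the median divided by 3, Hd-rR fed 6 dph replicate 4 with 291874 and NIES-R fed 4 dph replicate 5 with 699621. Every other library had at least 2219151 counts. Detected genes ranged from 15183 to 18028 outside the 2 shallow libraries. No pair of libraries within a group agreed within sampling noise, the closest pair having a chi-square of 4.23 per degree of freedom, so every library was counted as 1 replicate.

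The main test was edgeR 4.0.16 (quasi-likelihood F test, TMM normalization) in R 4.3.3, fitted once to all 108 libraries with 18 group means and 90 residual degrees of freedom. Genes were kept by filterByExpr with its minimum count of 10, which left 14491 genes holding 99.9% of the counts. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, separately for each comparison. All comparisons share the same estimate of the spread of a gene, so their lists of called genes are not strictly independent. Overlaps set against independent lists carry this limit. The comparisons were unfed against fed on each day and as the mean of the 4 days in each strain, the difference of these effects between the strains (NIES-R minus Hd-rR), the strains at hatching, and 8 dph against hatching for fed and for unfed fry of each strain. The standard error (SE) of a log2 fold change was its size divided by the square root of F. The CPM values printed and drawn for the named genes relate the count to the total count of the library and were not scaled by TMM. The log2 CPM values were scaled by TMM. Principal components were taken from log2 CPM (prior count 2) of the 2000 most variable tested genes, centred and not scaled. The comparisons, the tests, the gene filter, the rule for named genes and the alternatives were chosen before the data were examined, except where a sentence says otherwise.

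The script of the main test was tested on simulated data for the NIES-R comparison at 2 dph, with all 14491 genes. It recovered 22 of 100 genes changed 1.5-fold and 74 of 100 changed 3-fold, with 7 false calls among unchanged genes, and called 0 genes in a comparison without any change. From the same simulated counts limma recovered 16 and 68 genes with 1 false call, and DESeq2 recovered 25 and 75 with 22 false calls. Both were given only the libraries of the compared groups, while edgeR was fitted to the libraries of all groups. The numbers therefore do not compare the tools on equal terms. Nor do the 22 false calls measure the DESeq2 Wald test fitted to all libraries. In this simulation many genes changed 1.5-fold were missed by each tool. Only the genes counted above were changed, in 1 group. The adjusted threshold is less strict where more genes change, so these shares do not carry over to real comparisons with far more calls.

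The deposited table pairs no identifier with a gene name. The reference table used here, for assembly ASM223467v1, holds symbols and no Ensembl identifiers, and 0 of the 23649 identifiers could be matched. For this reason the 30 gene lists drawn up in advance could not be applied, and results are given by the number, direction and overlap of genes. Identifiers are printed for at most 2 genes that were higher and 2 that were lower in unfed fry. They are those with the largest and the most negative mean-of-4-days log2 fold change among genes called in that comparison, with a mean of at least 10 CPM and the same fitted sign on all 4 days. The rule had been written for each strain, and its narrowing to the extremes over both strains was made after the values were seen. Without names or sequences it is not known which genes share reads with near-identical copies or overlapping neighbours.

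The alternatives were DESeq2 size factors within edgeR, the DESeq2 1.42.0 Wald test, no filter on low counts, the replicate number as a block, fits with the compared groups alone, a fit without the 2 shallow libraries, and principal components of all tested genes. Several were added after the data had been seen. These are the mean over 2 and 4 dph alone, which uses no library of the second plate, the removal of each 2 dph library in turn, the removal of 1 Hd-rR unfed 2 dph library that stood apart, and the removal of each hatching library in turn for the strains at hatching. The comparison of the effect at 8 dph with that at 2 dph within a strain was also added then. Other splits of the same libraries were tested with limma 3.58.1 on log2 CPM, with 100 splits per comparison, the real one included. A response score per library, also added later, is the mean log2 CPM of 828 genes minus that of 1089 genes. The former were called higher and the latter lower in unfed fry at 8 dph in both strains, by at least 2-fold in each.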

Results

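The series asked how gene expression in newly hatched medaka changes when no food is given, in the strains NIES-R and Hd-rR. Whole-body RNA was profiled at hatching and then at 2, 4, 6 and 8 dph in fed and unfed fry, with 6 libraries in each of the 18 groups. Mean total counts per group lay between 3601000 ± 520000 (SD, n = 6) in NIES-R unfed fry of 4 dph and 5953000 ± 793000 in NIES-R unfed fry of 8 dph. The 12 Hd-rR unfed libraries of 6 and 8 dph, whose wells start again and are taken here as a second plate, had 4598000 ± 495000 and 4247000 ± 265000 counts.

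Food and strain lay on separate principal components. The first component held 26.7% of the variance, and the groups of food and day accounted for 89.7% of its scores. Fed NIES-R fry lay between -25.7 ± 6.10 (SD, n = 6) at 4 dph and -16.4 ± 3.79 at 2 dph, with -16.3 ± 3.92 at hatching. Fed Hd-rR fry went from -12.6 ± 6.70 at hatching to -18.6 ± 4.31 at 2 dph, -21.1 ± 3.83 at 4 dph, -14.2 ± 16.1 at 6 dph and -30.4 ± 1.72 at 8 dph. Unfed NIES-R fry moved to 0.293 ± 7.61 at 2 dph, 23.2 ± 14.3 at 4 dph, 29.8 ± 15.3 at 6 dph and 41.2 ± 12.4 at 8 dph. Unfed Hd-rR fry moved from -5.93 ± 11.3 at 2 dph to 17.1 ± 4.90 at 4 dph, 47.3 ± 4.11 at 6 dph and 44.9 ± 5.63 at 8 dph. The second component held 8.66% of the variance, and strain accounted for 96.5% of its scores. With all 14491 tested genes the strains separated on the third component instead, where strain accounted for 95% of the scores against 2.45% on the second. One Hd-rR fed 6 dph library, replicate 4, scored 18.1 on the first component, while the other 5 libraries of its group scored -23.4 to -15.4.

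**Figure D1:**
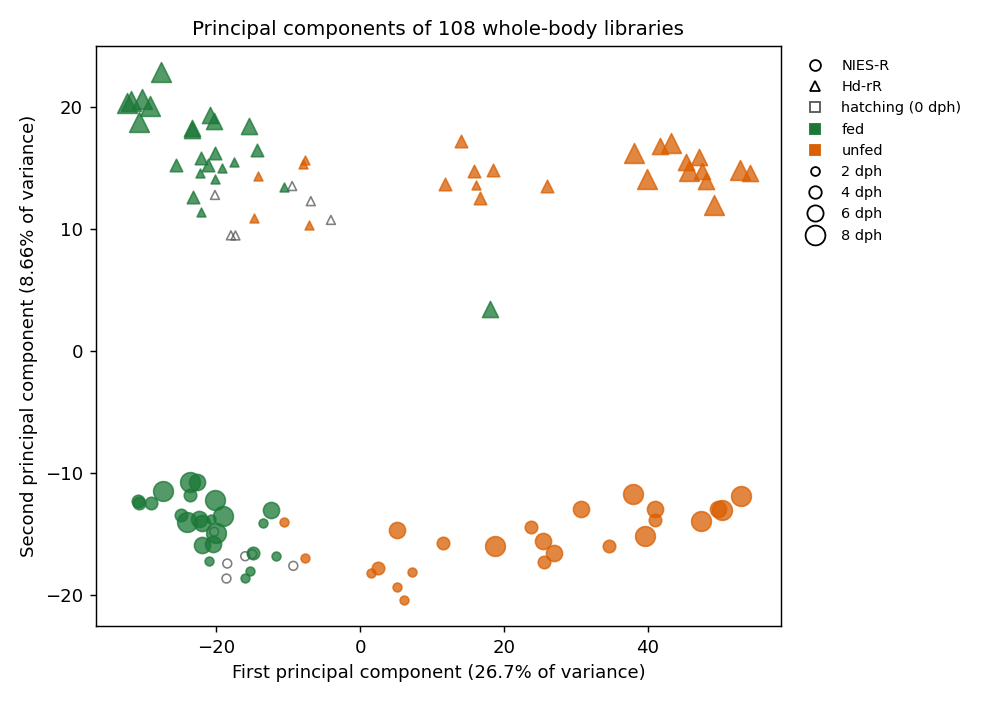
Principal component scores of all libraries, the first component on the horizontal axis (26.7% of variance) and the second on the vertical axis (8.66%), both without units. Circles are NIES-R and triangles Hd-rR, open grey symbols are hatching, green fed and orange unfed, and symbol size grows with day. Unfed libraries lie to the right, with means of 41.2 in NIES-R and 44.9 in Hd-rR at 8 dph, and the lone green triangle at 18.1 is Hd-rR fed 6 dph replicate 4.

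Lack of food changed more genes at 4, 6 and 8 dph than at 2 dph in both strains. In NIES-R, 1629 genes differed between unfed and fed fry at 2 dph, 780 higher and 849 lower in unfed fry (edgeR, adjusted p below 0.05). At 4 dph 5831 genes differed, 2979 higher and 2852 lower. At 6 dph there were 4939, with 2449 higher and 2490 lower, and at 8 dph 5986, with 3068 higher and 2918 lower. In Hd-rR the counts were 431 at 2 dph (153 higher, 35.5% of those called), 4279 at 4 dph (2126 higher, 2153 lower), 6332 at 6 dph (3198 higher, 3134 lower) and 7462 at 8 dph (3713 higher, 3749 lower). Among genes that differed by at least 2-fold, more were lower than higher in unfed fry on every day. In NIES-R 187 were higher and 193 lower at 2 dph, 1001 and 1370 at 4 dph, 714 and 1069 at 6 dph, and 1117 and 1482 at 8 dph. In Hd-rR the numbers were 49 and 72, 580 and 810, 1333 and 1564, and 1768 and 2134. The Hd-rR counts at 6 and 8 dph set libraries of the second plate against libraries of the first. With limma on the compared groups alone, the Hd-rR count was 3390 at 6 dph, below the 4456 at 4 dph. With edgeR on the compared groups alone the counts were 4854 at 6 dph and 4504 at 4 dph. In the edgeR fit without the 2 shallow libraries, 1 of them in Hd-rR fed 6 dph, they were 6525 and 4486. The counts at 2 dph were sensitive to single libraries. With 1 library left out at a time, in fits of the compared groups alone, they ran from 1030 to 1791 in NIES-R and from 133 to 390 in Hd-rR. The lowest counts came without NIES-R fed 2 dph replicate 6 and without Hd-rR fed 2 dph replicate 6.

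**Figure D2:**
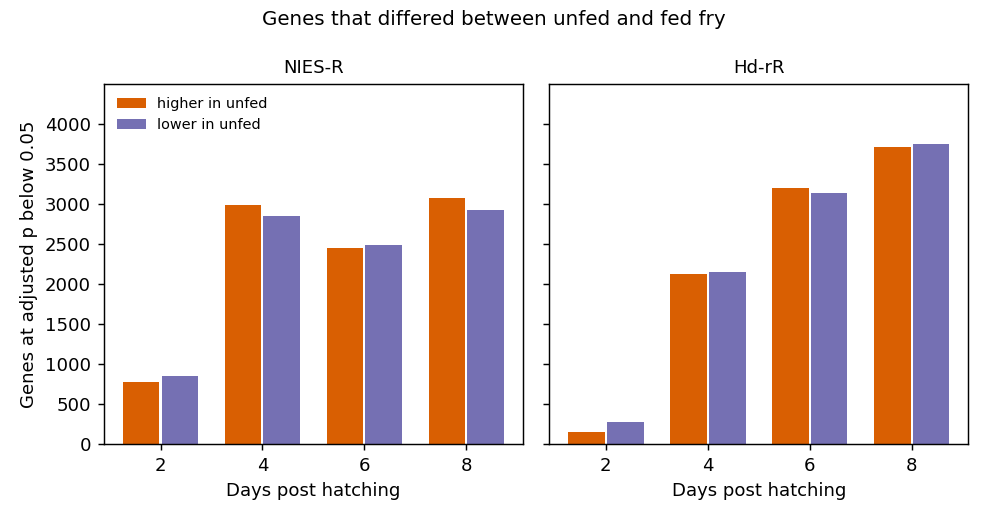
Number of genes that differed between unfed and fed fry at an adjusted p below 0.05 (vertical axis) by day after hatching (horizontal axis), NIES-R on the left and Hd-rR on the right. Orange bars are genes higher and purple bars genes lower in unfed fry, and in Hd-rR the orange bars rise from 153 genes at 2 dph to 3713 at 8 dph, where the purple bar stands at 3749.

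The effect itself changed between the first and the last day. The unfed against fed effect differed between 8 and 2 dph for 2742 genes in NIES-R, 1305 more positive and 1437 more negative at 8 dph, and for 4242 genes in Hd-rR, 2119 more positive and 2123 more negative. In Hd-rR the unfed libraries of 8 dph are taken to come from a second plate, and the other libraries compared are not. A plate effect cannot be told apart from the change of the effect with day in that strain. Genes called on the earliest day mostly kept their direction. Of the 780 genes higher at 2 dph in NIES-R, 587 were also called higher at 4 dph and 489 at 8 dph, where independent lists would share 160 and 165. Of the 849 lower genes, 697 and 471 were called lower on those days, against 167 and 171. In Hd-rR, 120 of the 153 higher genes of 2 dph were also called higher at 8 dph, against 39.2 for independent lists, and 81.3% of the lower genes were also called lower. Comparisons on different days within a strain used different libraries. They share the estimate of the spread of each gene, so the numbers for independent lists are not a strict baseline. Over all 4 days, 426 genes were called higher and 411 lower each day in NIES-R, and 74 higher and 171 lower in Hd-rR. At 4, 6 and 8 dph alone these numbers were 1448 and 1452 in NIES-R and 1360 and 1426 in Hd-rR. Of the genes called on 2 or more days, 199 of 5467 in NIES-R and 165 of 6004 in Hd-rR were called higher on one day and lower on another.

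Averaged over the 4 days, 8391 genes differed in NIES-R (4305 higher, 4086 lower) and 8719 in Hd-rR (4457 higher, 4262 lower). Without the later days, on 2 and 4 dph alone, the Hd-rR count was 4104 and the NIES-R count 5677.

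ENSORLG00000005696 had one of the largest mean increases in unfed fry, 3.96 ± 0.222 (log2 fold change ± SE) in NIES-R (edgeR adjusted p = 6.84e-30) and 3.06 ± 0.215 in Hd-rR (adjusted p = 5.27e-24). In NIES-R it already stood at 235.5 ± 92.1 CPM (SD, n = 6) in unfed fry of 2 dph, against 21.9 ± 2.06 in fed fry, and at 8 dph at 414 ± 102 against 26.1 ± 2.74. In Hd-rR the 8 dph means were 401 ± 48.1 and 20.4 ± 2.31 CPM. At 2 dph the Hd-rR unfed libraries spread widely, replicate 2 at 349 CPM and the other 5 between 19.8 and 50.5, with 23.9 ± 10.1 in fed fry. The Hd-rR effect at 2 dph was 1.81 ± 0.416 with all libraries (edgeR adjusted p = 0.00463) and 0.33 ± 0.359 without replicate 2 (adjusted p = 0.776). The strain difference at 2 dph moved from 1.75 ± 0.577 (adjusted p = 0.11) to 3.20 ± 0.499 (adjusted p = 5.39e-06) without that library. At 6 dph it passed the test at 1.87 ± 0.570 (edgeR adjusted p = 0.0361), and not without the 2 shallow libraries (1.57 ± 0.561, adjusted p = 0.086). For the mean of the 4 days the strain difference was 0.90 ± 0.287 (adjusted p = 0.0567). Its adjusted p lay between 0.0303 and 0.291 under the alternatives and was 0.000312 without Hd-rR unfed 2 dph replicate 2. The gene was chosen by its NIES-R value, which favours a difference of this sign.

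ENSORLG00000005665 rose in the same comparison by 4.02 ± 0.283 in NIES-R (edgeR adjusted p = 1e-23) and by 2.11 ± 0.275 in Hd-rR (adjusted p = 7.46e-11), on the log2 scale. Its level in unfed NIES-R fry was 25.5 ± 9.26 CPM at 2 dph and 24.2 ± 12.9 at 8 dph, against 0.973 ± 0.495 and 2.25 ± 1.74 in fed fry. In Hd-rR it was 15.2 ± 4.76 CPM in unfed and 0.978 ± 1.07 in fed fry at 8 dph. By day, the Hd-rR effect passed the test at 4 dph (2.98 ± 0.534, adjusted p = 4.62e-06) and 8 dph (3.69 ± 0.593, adjusted p = 8.61e-08). It did not at 2 dph (1.17 ± 0.564, adjusted p = 0.274) or 6 dph (0.61 ± 0.495, adjusted p = 0.332). Without Hd-rR unfed 2 dph replicate 2 the 2 dph effect was 0.43 ± 0.591 (edgeR adjusted p = 0.845). The mean increase over the 4 days was larger in NIES-R than in Hd-rR by 1.91 ± 0.403 (edgeR adjusted p = 0.00136). The gene was chosen by its NIES-R value, which favours a difference of this sign. The strain difference of single days passed the test at 2 dph (3.65 ± 0.834, adjusted p = 0.00649) and 6 dph (2.90 ± 0.715, adjusted p = 0.00654). At 8 dph it was -0.37 ± 0.797 (adjusted p = 0.877). The Hd-rR fed fry of 6 dph had 8.69 ± 7.50 CPM, with single libraries from 1.52 to 21.4.

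ENSORLG00000020002 was lower in unfed fry of both strains, with a mean log2 fold change over the 4 days of -4.05 ± 0.247 in NIES-R (edgeR adjusted p = 1.43e-27) and -4.39 ± 0.240 in Hd-rR (adjusted p = 6.17e-31). At 8 dph its level was 0.933 ± 0.689 CPM in unfed and 57.8 ± 15.3 in fed NIES-R fry, and 2.17 ± 1.62 and 121 ± 17.6 CPM in Hd-rR. Both arms had moved away from hatching, where NIES-R had 20.3 ± 9.52 and Hd-rR 20.4 ± 6.37 CPM. From hatching to 8 dph it rose in fed fry, by 1.72 ± 0.390 in NIES-R (adjusted p = 0.000477) and 2.67 ± 0.395 in Hd-rR (adjusted p = 1.5e-07). In unfed fry the change was -4.29 ± 0.545 (adjusted p = 1.15e-10) and -3.29 ± 0.506 (adjusted p = 4.94e-08). At 2 dph the effect of food passed the test in Hd-rR (-2.03 ± 0.402, adjusted p = 0.000984) and not in NIES-R (-0.89 ± 0.421, adjusted p = 0.175), with a strain difference of 1.14 ± 0.580 that did not pass it (adjusted p = 0.389). In NIES-R unfed fry of 2 dph replicate 6 stood apart at 27.8 CPM. The other libraries of that group had 1.44 to 8.95 CPM, below the 9.25 to 33.2 of the fed libraries. The strain difference of the mean effect was 0.33 ± 0.374 (adjusted p = 0.732).

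ENSORLG00000019564 was lower in unfed fry by another route, since its unfed level stayed near that of hatching while fed fry rose. Fed fry of 8 dph had 157 ± 114 CPM in NIES-R, with 1 of the 6 libraries at 0.927, and 294.5 ± 153 in Hd-rR. Hatching fry had 1.42 ± 0.614 and 1.70 ± 0.559 CPM, and unfed fry of 8 dph 1.29 ± 0.776 and 1.82 ± 0.739. The rise from hatching to 8 dph in fed fry was 6.94 ± 0.610 in NIES-R (edgeR adjusted p = 4.25e-16) and 7.53 ± 0.609 in Hd-rR (adjusted p = 8.7e-18). The change in unfed fry was -0.09 ± 0.813 (adjusted p = 0.949) and 0.06 ± 0.787 (adjusted p = 0.961). The effect of food did not pass the test at 2 dph in NIES-R (-0.27 ± 0.915, adjusted p = 0.908) or Hd-rR (-1.05 ± 0.744, adjusted p = 0.528), nor at 4 dph in NIES-R (-1.005 ± 0.764, adjusted p = 0.307). At 6 dph the fed level was 5.97 ± 4.88 CPM in NIES-R and 125 ± 130 in Hd-rR, and the strain difference of the food effect was 4.66 ± 0.958 (adjusted p = 0.000862). As the mean of the 4 days it was 1.74 ± 0.528 (adjusted p = 0.0408), against 0.0548 in the fit of the compared groups alone and 0.0515 without Hd-rR unfed 2 dph replicate 2. Its adjusted p lay between 0.00522 and 0.722 under the alternatives, the highest being that of 2 and 4 dph alone. The gene was chosen by its Hd-rR value, which favours a difference of this sign.

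**Figure D3:**
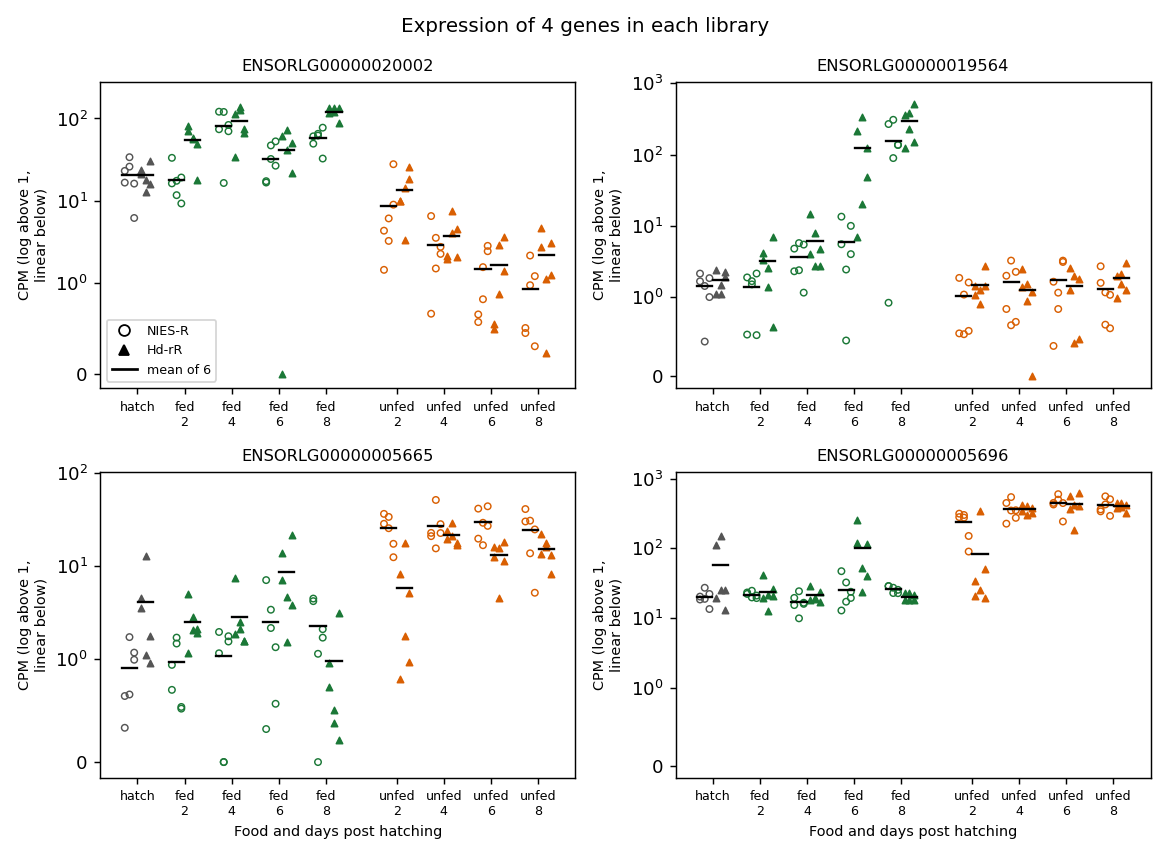
Expression of 4 genes in each library, in CPM on a vertical axis that is logarithmic above 1 and linear below it, by food and day on the horizontal axis. Open circles are NIES-R, filled triangles Hd-rR, and black lines the mean of 6 libraries. ENSORLG00000020002 ends at 0.933 and 2.17 CPM in unfed fry of 8 dph, ENSORLG00000019564 reaches 157 and 294.5 CPM in fed fry of 8 dph, and ENSORLG00000005696 reaches 414 and 401 CPM in unfed fry of 8 dph.

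The strains shared more called genes than independent lists would on each day. Both lists come from the same fit with a shared estimate of the spread per gene, so independence is not a strict baseline. At 2 dph 51 genes were called higher and 107 lower in both strains, against 8.24 and 16.3 for independent lists of those lengths. Of the genes called in NIES-R on that day, 74.1% of the higher and 79.9% of the lower ones had the same sign in Hd-rR. At 4 dph 1572 were higher and 1669 lower in both, against 437 and 424. At 6 dph 1776 were higher and 1831 lower, against 540 and 539, and at 8 dph 2485 and 2353, against 786 and 755. Few genes were called in opposite directions in the strains at 8 dph, 14 of those higher and 18 of those lower in NIES-R. Across the 14491 genes, which are not independent replicates, Pearson's r between the log2 fold changes of the strains was 0.158 at 2 dph, 0.640 at 4 dph, 0.623 at 6 dph, 0.772 at 8 dph and 0.837 for the mean of the 4 days. The strains share no libraries. Without the filter on low counts these values were 0.04, 0.24, 0.28, 0.43 and 0.55.

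Strain differences of the food effect, tested directly, were found for fewer genes. Such a difference has a larger SE than the effect in either strain, so fewer calls do not by themselves show like responses. For ENSORLG00000005665 and the mean of the 4 days it was 0.403, against 0.283 in NIES-R and 0.275 in Hd-rR. At 2 dph they made up 1.51% of the tested genes, 127 more positive and 92 more negative in NIES-R, and at 4 dph they numbered 150 (84 and 66). At 6 dph they numbered 706 (384 and 322), at 8 dph 639 (54.8% of them more positive), and for the mean of the 4 days 548 (51.6% more positive). The mean over 2 and 4 dph alone, which uses no library of the second plate, gave 65 genes. The DESeq2 Wald test called 344 genes at 2 dph (2.37% of those tested) and 1.61% of the same genes at 4 dph, where the edgeR calls made up 1.04%, and the fit of the 4 compared groups alone called 352 at 6 dph. At 6 and 8 dph the second plate holds all Hd-rR unfed libraries and no others, so no fit can hold the plate as a term beside the strain difference there.

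Before any difference in food, at hatching, counts of 901 genes differed between the strains, 500 higher and 401 lower in NIES-R, and 353 of them differed by at least 2-fold. How far a difference in read matching between the strains enters this number was not tested. Fitted with the 12 hatching libraries alone, the comparison called 551 genes. The strain difference at hatching was -1.64 ± 0.420 for ENSORLG00000005696 (edgeR adjusted p = 0.00713) and -2.21 ± 0.651 for ENSORLG00000005665 (adjusted p = 0.0235), on the log2 scale. Both calls rested on single libraries. Without Hd-rR hatching replicate 2 the values were -1.06 ± 0.415 (adjusted p = 0.145) for ENSORLG00000005696 and -1.43 ± 0.684 (adjusted p = 0.285) for ENSORLG00000005665. Without replicate 4 the value of ENSORLG00000005696 was -1.30 ± 0.428 (adjusted p = 0.0619). For this gene replicates 2 and 4 had 151 and 111 CPM, and the other 4 Hd-rR libraries 13.3 to 25.7, where the NIES-R libraries had 13.6 to 27.4.

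From hatching to 8 dph more genes changed in unfed than in fed fry. In NIES-R 3036 genes changed in fed fry (1556 higher, 1480 lower at 8 dph) and 5841 in unfed fry (2910 higher, 2931 lower). In Hd-rR the counts were 2658 in fed fry (1312 higher, 1346 lower) and 5606 in unfed fry (2738 higher, 2868 lower). The Hd-rR unfed libraries of 8 dph are taken to come from a second plate, and the hatching and fed ones are not. A plate effect therefore cannot be told apart from the change in unfed Hd-rR fry. In unfed fry 1929 genes were called higher and 2113 lower in both strains, against 550 and 580 for independent lists. In fed fry 575 were higher and 501 lower in both, against 141 and 137. Among the 3068 genes higher in unfed than fed NIES-R fry at 8 dph, the median log2 change from hatching in Hd-rR was 0.62 in unfed and -0.28 in fed fry. Among the 2918 lower genes it was -0.76 in unfed and 0.29 in fed fry. For the 3713 higher and 3749 lower genes of Hd-rR, the medians in NIES-R were 0.53 and -0.68 in unfed fry, and -0.12 and -0.01 in fed fry.

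The response score placed each library on the scale of the change shared by both strains at 8 dph. In NIES-R it rose over the mean of the fed fry of the same day by 0.738 ± 0.309 (SD, n = 6) at 2 dph, 2.28 ± 0.655 at 4 dph, 2.28 ± 0.720 at 6 dph and 3.29 ± 0.586 at 8 dph. In Hd-rR the rises were 0.634 ± 0.482, 1.66 ± 0.231, 2.93 ± 0.233 and 3.77 ± 0.272. All 6 unfed NIES-R libraries and 4 of 6 unfed Hd-rR libraries of 2 dph lay above the highest fed library of their strain and day, and from 4 dph on all unfed libraries of both strains did. The genes of the score were chosen from the libraries of 8 dph, so the separation on that day is built in.

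**Figure D4:**
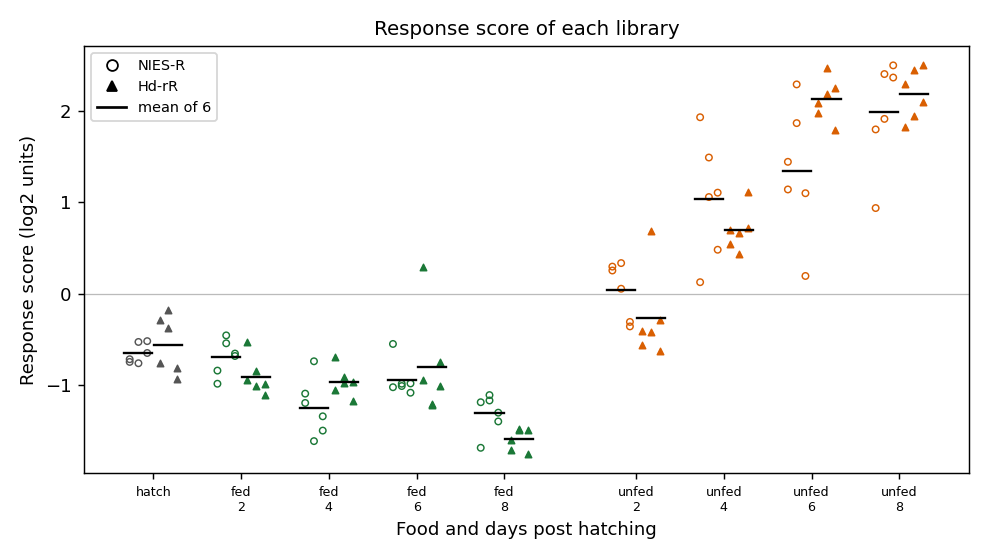
Response score of each library in log2 units (vertical axis), the mean log2 CPM of genes higher minus that of genes lower in unfed fry of 8 dph, by food and day (horizontal axis). Open circles are NIES-R, filled triangles Hd-rR, and black lines the mean of 6 libraries. Unfed means rise over fed means by 0.738 and 0.634 at 2 dph and by 3.29 and 3.77 at 8 dph, and the highest fed library, at 0.290, is Hd-rR fed 6 dph replicate 4.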

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

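The strain differences by day and for the mean, and the fit without the 2 shallow libraries, were planned, and the test of equal total counts at 2 dph was set before its result was seen. All other tests in this part, and the use of that fit for the 6 dph count, were chosen after the results they bear on were seen. In 19 of 144 groups of 6 values, 1 library stood apart by Dixon's test. Chance gives this in about 1 group in 20. For the total count these were NIES-R fed 4 dph replicate 5 (699621, the others 4629145 to 5662219), NIES-R unfed 8 dph replicate 1 (4434267, the others 5929046 to 6622447) and Hd-rR fed 4 dph replicate 5 (2375179, the others 4234151 to 5165972). On the first principal component they were NIES-R fed 6 dph replicate 4 (-12.4), Hd-rR fed 6 dph replicate 4 (18.1) and Hd-rR unfed 2 dph replicate 2 (16.2, the others -14.7 to -7.15). On the second they were NIES-R fed 4 dph replicate 2 (-16.6), Hd-rR fed 4 dph replicate 1 (12.6) and Hd-rR fed 6 dph replicate 4 (3.42, the others 18.1 to 19.4). The response score set apart the same 3 libraries as the first component, at -0.549 for NIES-R fed 6 dph replicate 4, 0.290 for Hd-rR fed 6 dph replicate 4 and 0.680 for Hd-rR unfed 2 dph replicate 2.

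Among the named genes, ENSORLG00000020002 was at 27.8 CPM in NIES-R unfed 2 dph replicate 6 and at 1.44 to 8.95 in the others. ENSORLG00000019564 was at 2.72 CPM in Hd-rR unfed 2 dph replicate 6. ENSORLG00000005665 was at 51.1 CPM in NIES-R unfed 4 dph replicate 2, 12.8 in Hd-rR hatching replicate 2, 7.32 in Hd-rR fed 4 dph replicate 4 and 3.09 in Hd-rR fed 8 dph replicate 6. ENSORLG00000005696 was at 349 CPM in Hd-rR unfed 2 dph replicate 2 and at 19.8 to 50.5 in the others. Differences of the effect between strains, each by its own test, were found for 1.51% of the tested genes at 2 dph, 1.04% at 4 dph, 4.87% at 6 dph, 4.41% at 8 dph and 3.78% for the mean, and included ENSORLG00000019564 (1.74) and ENSORLG00000005665 (1.91). The effect differed between 8 and 2 dph for 2742 genes (18.9%) in NIES-R and 4242 (29.3%) in Hd-rR. In Hd-rR only the unfed libraries of 8 dph are taken to come from a second plate, so plate and day cannot be told apart.

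In the edgeR fit of all groups the strain difference of the food effect covered more genes at 6 and 8 dph, when the Hd-rR unfed libraries came from what is taken as a second plate, than before, which with limma on the compared groups alone held at 8 dph (967 genes) and not at 6 dph (121, against 151 at 2 dph and 175 at 4 dph). A plate effect would act on the unfed arm, yet the change from hatching to 8 dph differed more between the strains in the unfed than in the fed arm for 25.5% of the 639 genes (24.1% to 29.4% with any 1 hatching library left out), which argues against the plate as the source of most of that difference. The 110 genes called on both days, against 31.1 for independent lists and 109 of them with the same sign, are what a plate effect would also give. Days without such libraries also shared more than independent lists would, 10 genes against 2.27 at 2 and 4 dph, but 1 of these 10 had the same sign. Among the 110 genes the share was 40.9% (22.3% among the other 529), so the plate stays open for a part of them. At 6 dph the share was 56.8%, between the 85.8% of 2 dph and the 41.3% of 4 dph, days without such libraries, so there the plate and the strains cannot be told apart. Without the shallow libraries edgeR called 699 genes at 6 dph, against 158 more positive and 134 more negative at 2 dph, which argues against the shallow Hd-rR fed library as the source of the edgeR count, and a strain difference in the response remains open at both days.

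Hd-rR fed 6 dph replicate 4 lay between the fed and the unfed libraries and between the strains. Its counts were concentrated, 38.5% of them in its own 10 most abundant genes and 20.0% in the first of these. A random loss of reads leaves such a share in place, and the highest share among the other 5 libraries of its group was 16.4%, which argues against low depth alone. A mixture of other libraries of the pool cannot exceed the highest share among them, which was 18.2% over all other libraries, so carried-over reads do not account for it either. A fault in the RNA or in the reaction of this sample stays open, and no biological explanation was tested.

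At 2 dph NIES-R had 1629 called genes and Hd-rR 431. With the strains fitted separately the counts were 1559 and 327, and with all 24 libraries thinned to 3129622 counts 1504 and 318, so total counts do not explain the difference. In such fits with any 1 library left out, at least 1030 genes were called in NIES-R and at most 390 in Hd-rR, so no single library does either. An earlier response in NIES-R may be a reason, but the response score rose by 0.738 in NIES-R and 0.634 in Hd-rR (exact permutation test of the unfed libraries, 2-sided p = 0.682, Benjamini-Hochberg adjusted over the 4 days 0.682), and by 0.444 in Hd-rR without replicate 2, with a difference of 0.295 (exact p = 0.0866). The score leaves this open, as it does the possibility that the strains change different genes on that day.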

How the results depend on the processing

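The mean over 2 and 4 dph, the removal of each 2 dph library in turn, the removal of the 2 dph library that stood apart and the removal of each hatching library were chosen after the results were seen. Of 135 alternative counts for 22 comparisons, fits with 1 library left out not included, 129 stayed within 1.5 times the reported count. The 6 others, some of them given with the results, are given here as percentages of the 14491 genes tested with all libraries. They were 28.3% (4104 genes) for the mean effect in Hd-rR over 2 and 4 dph alone, 0.449% (65) for the mean strain difference over those days, 2.37% and 1.61% for the strain difference at 2 and 4 dph with the DESeq2 Wald test, 2.43% (352) for that at 6 dph and 3.80% (551) for the strains at hatching when the compared groups were fitted alone. The compared groups alone had 13167 and 12234 genes to test in the last pair. What moved these counts was not tested. With 1 library of 2 dph left out the count ran from 1030 to 1791 in NIES-R (7.11% to 12.4% of the same 14491 genes) and from 133 to 390 in Hd-rR (0.918% to 2.69%), and with 1 hatching library left out the strains at hatching differed in 602 to 950 genes. DESeq2 size factors moved the share of higher calls by at most 6 percentage points and the median log2 fold change of all genes by at most 0.0347.

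Of 84 alternative values for the named genes, all kept their direction and 78 their side of the threshold. The strain difference of ENSORLG00000005696 passed it with the DESeq2 Wald test (adjusted p = 0.0341) and with the compared groups alone (0.0303). For ENSORLG00000019564 the NIES-R effect over 2 and 4 dph alone was -0.64 ± 0.598 (edgeR adjusted p = 0.424). Of 31 correlations between the strains 22 stayed within 0.1. Without the filter they were 0.038, 0.241, 0.281, 0.427 and 0.55 at 2, 4, 6 and 8 dph and for the mean. With the compared groups alone they were 0.261, 0.792 and 0.768 at 2, 4 and 6 dph, and over 2 and 4 dph alone the mean gave 0.654. The first 2 settings also alter which genes are tested, and the cause was not tested further. With all genes the first principal component held 21.9% of the variance, and strain accounted for 2.45% of the second.

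The labels do not say whether replicate numbers pair the samples, and no strong pairing was seen. The mean correlation of the deviations of fed and unfed libraries with the same number lay between -0.0161 and 0.0338 over the 8 strain and day pairs, in 0 of which every pair was above 0.1, and 11 of 48 fed libraries correlated best with their own number. By strain and day, the fed libraries that correlated best with their own number were 3 in Hd-rR at 6 dph and 3 at 8 dph. In the other strain and day pairs they were 0 to 2, so a weak pairing is not excluded. With the replicate block the counts were 0.993 to 1.09 times those reported, and the strain difference of ENSORLG00000005696 was 0.93 ± 0.275 (adjusted p = 0.0341). Tests of the 30 gene lists were not run, since no identifier has a symbol. Depth limits genes with few counts, since 1 library holds 699621 counts, another still fewer, and each of the others at least 2219151.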

Other observations

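All tests in this part were chosen after the results were seen. Genes that changed with age in fed fry of one strain tended to be held back or turned by lack of food in the other strain, which shares no libraries with it. Of the 1556 genes that rose from hatching to 8 dph in fed NIES-R fry, 637 were called lower in unfed than in fed Hd-rR fry of 8 dph, so that 68.4% of those called went against the change with age. Of the 1480 that fell, 605 were higher (59.8%). Of the 1312 genes that rose in fed Hd-rR fry, 718 were lower in unfed NIES-R fry (90.5%), and of the 1346 that fell, 749 were higher (89.6%). In 1000 random sets of genes of the same size for each of the 4 the share stayed between 42.5% and 57.2%. Genes were drawn there as if they varied independently, so this range does not measure the uncertainty of the 4 shares. The lowest of the 4 shares, 59.8%, is consistent with a response to fasting that includes a lack of the changes fed fry go through. The median log2 change from hatching for the genes that rose in fed fry was 0.16 in unfed Hd-rR against 0.41 in fed Hd-rR, and -0.12 in unfed NIES-R against 0.52 in fed NIES-R. The values measured in unfed Hd-rR fry use libraries taken to come from a second plate, and those measured in NIES-R do not.

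At 4, 6 and 8 dph the response score spread more between unfed libraries of NIES-R than of Hd-rR, and at 2 dph, with all libraries, it did not. Over 4, 6 and 8 dph the mean distance of a library from the median of its group was 0.480 in NIES-R and 0.183 in Hd-rR (18 libraries each, permutation test within days with 100000 resamples, 2-sided p = 0.00385). At 2 dph the distances were 0.249 and 0.266 (exact permutation p = 0.944), and with that day included they were 0.422 and 0.204 (24 libraries each, 2-sided p = 0.0164). The Hd-rR spread at 2 dph leaned on replicate 2. Without it the SD of the rise was 0.138 in Hd-rR, against 0.482 with it and 0.309 in NIES-R. Exact tests on the 3 later days gave p = 0.106, 0.108 and 0.171 (Benjamini-Hochberg adjusted with 2 dph 0.216, 0.216 and 0.228). A candidate explanation is that NIES-R fry, or the tanks or pools they came from, differ more in how far the response has gone, which the labels do not let be tested further. The unfed Hd-rR libraries of 6 and 8 dph are those taken here to come from a second plate.

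The rise of the score did not differ between the strains past the threshold once adjusted. The difference, NIES-R minus Hd-rR, was 0.619 at 4 dph (exact permutation test of the unfed libraries with the fed means held fixed, 2-sided p = 0.0541), -0.652 at 6 dph (exact p = 0.0498) and -0.480 at 8 dph (exact p = 0.0801), with an adjusted value of 0.107 on each of the 3 days. Without Hd-rR fed 6 dph replicate 4, the library that stood apart, the 6 dph difference was -0.871 (exact p = 0.0173, adjusted 0.0693).

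The genes with a strain difference were partly shared between 6 and 8 dph. Among those called on both days were 110 genes, against 31.1 for independent lists, and 109 of them had the same sign. The lists of all days come from the same fit with a shared estimate of the spread per gene, so independence is not a strict baseline. Every other pair of days also shared more genes than independent lists would, such as 10 against 2.27 at 2 and 4 dph. Same signs were rarer there, from 1 of 10 at 2 and 4 dph to 12 of 23 at 2 and 6 dph. Across all genes Pearson's r between the strain differences of the 2 days was 0.241, against -0.0566 to 0.0435 for the other pairs of days. These days are also the ones with libraries on the second plate.

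A set of 10 genes that varied together was chosen after the values were seen, starting from the gene with the greatest fold difference between the strains at hatching and taking genes whose deviations from the group means correlated with it by at least 0.7. Their summed level stayed at or below 246.5 CPM in all 48 fed libraries, with a median of 164.8. It exceeded that level in 14 of the 24 unfed libraries of 6 and 8 dph, in 1 of the 24 unfed libraries of 2 and 4 dph and in 1 of the 12 hatching libraries, NIES-R replicate 6 at 2082 CPM, with the 11 others at 97.8 to 155. The choice favours genes that vary widely between libraries of a group, so their spread is no separate finding.

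Other splits of the same libraries, 100 per comparison with the real one included, were run with limma on the compared libraries alone. In each of the 22 comparisons 1 of the 100 splits, the real one, called as many genes as the real one. Chance can be excluded only to that share in each comparison, without adjustment over the 22. A split that mixes the groups also carries their difference into its residual spread, which lowers its count. The real count and the highest of the other splits for unfed against fed NIES-R fry were 1399 and 533 at 2 dph, 4856 and 0 at 4 dph, 4930 and 1816 at 6 dph, 6088 and 3 at 8 dph and 8369 and 3 for the mean of the 4 days. For Hd-rR they were 330 and 11 at 2 dph, 4456 and 111 at 4 dph, 3390 and 0 at 6 dph, 7722 and 0 at 8 dph and 7932 and 2 for the mean of the 4 days. For the strain difference they were 151 and 17 at 2 dph, 175 and 1 at 4 dph, 121 and 1 at 6 dph, 967 and 1 at 8 dph and 370 and 1 for the mean. At hatching they were 610 and 33. For 8 dph against hatching they were 3152 and 8.44% of that count in fed and 5822 and 1 in unfed NIES-R, and 2577 and 8 in fed and 5575 and 1692 in unfed Hd-rR. For the effect at 8 dph minus that at 2 dph they were 2950 and 1 in NIES-R and 4466 and 1 in Hd-rR. The strain difference at 6 dph had fewer calls here than in the edgeR fit of all groups, and fewer than at 2 and 4 dph, and the Hd-rR effect at 6 dph had fewer calls than that at 4 dph. With edgeR on the compared groups alone the Hd-rR effect had more calls at 6 dph (4854) than at 4 dph (4504).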
